A study of Mus musculus with 10 samples.

How the data were processed

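Open chromatin was measured by ATAC-seq in mouse ES-Bruce4 embryonic stem cells, a C57BL/6 line, taken through differentiation toward neuromesodermal progenitors, the caudal cells that feed both spinal cord and paraxial mesoderm. Per the labels, the cells were grown with bFgf, with the Wnt pathway activator CHIR99021 added from day 2. Human Gdf11, a TGF-beta family ligand, was given at 50 ng/ml on day 6 for 24 h to 1 of the day 7 groups. The 5 groups were day 2, day 3, day 6, day 7 and day 7 with Gdf11, each with 2 libraries, which makes 10 libraries. The labels do not say whether the libraries of a group came from separate cultures, so each p-value measures the spread between these libraries.

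The deposited counts are raw counts per region, 1 value for each of 246799 regions and library, and the counter used is not stated. Per the labels the authors used HISAT2 2.1.0, SAMtools, MACS2 2.1.1.20160309, bedtools and HOMER 4.10 on build mm10, with no role or order stated for any of them. The deposited peak list of each library gives each peak a ratio, its fold enrichment over the background of the caller. The same lists as deposited give each peak the -log10 of its q, which the authors made by calling peaks per library. The deposited motif tables give the enrichment score of each motif as the natural log of a p-value, checked on 47 motifs against a binomial test from the same line, with ratios between 0.998 and 1.002. Other deposited motif values are numbers and percents of target and background sequences with the motif. The authors' choice of target regions for the motif tables is not stated.

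The count tables carry no coordinates. Merging the 10 deposited peak lists in character order of chromosomes gave 246799 regions, as many as were counted, and no library had a count of 0 in a region that held one of its own peaks. Numeric chromosome order left between 1110 and 9822 such zeros per library. Positions therefore rest on this match. Regions had a median width of 184 bp. The gene table held 21887 protein-coding genes of the same build with start and end but no strand. The planned use of transcription start sites was replaced: a region was assigned to the nearest gene span within 50 kb, which covered 190587 regions, of which 121334 lay inside a span. A region near a gene end lay within 1 kb of either end of a gene. Assignment by distance does not show that a region acts on the gene, and a gene's value is the accessibility of its assigned regions and not its expression.

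Counts were tested in edgeR 4.0.16 under R 4.3.3 by quasi-likelihood F tests (two-sided), with filterByExpr, TMM factors and 1 fit of all 10 libraries by group. The filter left 173175 regions and removed 73624. The common dispersion was 0.0402 and the prior degrees of freedom were 52.2, so the spread of 2 libraries per group was moderated by that of all regions. Gene values were sums over assigned regions with the library sizes and factors of the region table, and 18948 genes were tested. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Standard errors were derived from the F statistic, and counts scaled by library size (CPM) carry the SD of 2 libraries. A fold against a group with no counts was bounded by 3 counts over that group. Intervals and floors cover counting error only.

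Fixed before the data were examined were the groups, the 5 comparisons, the tests, the first set of alternatives, 15 gene lists and the rule for named genes. The lists were pluripotency and epiblast, caudal epiblast and neuromesodermal progenitor, presomitic and paraxial mesoderm, neural progenitor and spinal cord, TGF-beta and Smad response, Wnt targets, trunk-to-tail transition, Hox paralogue groups 1 to 4, 5 to 9 and 10 to 13, markers of endoderm, of lateral plate, heart and blood, of neural crest and of feeder fibroblasts, and housekeeping genes. All 236 distinct list genes were in the gene table. Some lists share genes. Sp5, Cdx1, T and Wnt3a are in both the caudal and the Wnt list, and Fgf8 and Cyp26a1 in both the caudal and the trunk-to-tail list. Results of such lists are not independent. Fibroblasts were listed because the stem cells were kept on mouse embryo fibroblasts before plating. The rule named up to 4 members per list with the smallest p past the threshold, the 5 genes per direction outside the lists with the largest change among those above the median abundance and without overlap between groups, any Hox gene, 3 regions per direction and the first 5 motifs of each deposited table. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 75 list tests, with the estimated correlation beside it. None of the 30 list calls held at 0.05 with an estimated correlation. This was so for the pluripotency list too, whose estimated correlation of -0.0141 lay below the preset one. Its unadjusted camera p at day 6 against day 3 still went from 1.68e-07 to 0.0023. The loss of calls is therefore not due to correlation alone, and what else differs between the settings was not separated. Values with an estimated correlation thus do not measure the effect of correlation by itself.

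Alternatives were DESeq2 1.42.0, RLE factors, library size only, cyclic loess offsets, no filter, only the 4 libraries of a comparison, the replicate number as an added term, that term together with cyclic loess offsets, a fold change of at least 2, gene windows of 10 kb or of 1 kb around gene ends, and each library left out in turn. Where 1 library of a group is left out, the remaining library is assumed to vary like the other groups. Gene-level and list-level cyclic loess and the removal of the 4 mitochondrial regions were chosen after seeing the data. Nearness to gene ends is given as the odds ratio of Fisher's exact test without its p, since regions are not independent. Peak overlap of at least 1 bp used bedtools 2.31.1. Random lists matched on abundance were drawn 10000 times from 50 abundance bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.

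On simulated data with the dispersion, depth and layout of the Gdf11 comparison, 22% of regions raised 2-fold and 18% of regions lowered 2-fold were recovered, and 88% and 62% at 4-fold, with 3 false calls among 163783 unchanged regions. All 50 genes of each kind were recovered at both folds, with 14 false calls among 18748 genes. A list shifted by 0.5 log2 units was called and 0 other lists were. Simulated genes were drawn independently, while estimated correlations in the real lists reached 0.399. The list simulation therefore does not test false list calls under such correlation. Changed regions and genes were drawn from those above the median abundance, and a changed gene had its whole sum changed. Single regions of that abundance that changed 2-fold are therefore mostly missed in such data. Gene sums that changed 2-fold as a whole are not, and a change in only some regions of a gene was not simulated.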

Results

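Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open DNA, in mouse embryonic stem cells on their way to neuromesodermal progenitors. The 10 libraries form 5 groups of 2: day 2 (epiblast-like cells), day 3, day 6, day 7, and day 7 after 24 h of Gdf11. Totals over the 246799 regions ran from 7150334 counts (day 3, replicate 2) to 12335735 (day 6, replicate 1), and the Gdf11 libraries held 10927890 and 9285217. Mitochondrial regions took between 9.25% (day 7, replicate 1) and 13.42% (day 2, replicate 2) of the counts. The deposited peak lists held from 80504 (day 6, replicate 2) to 118603 peaks (day 2, replicate 1), and 71.9% ± 9.5 of a library's peaks (SD over 10 libraries) overlapped a peak of the other library of its group. Spearman correlations between the libraries of a group were 0.85 to 0.887 across regions, which are not independent replicates. Those between day 6 and untreated day 7 libraries were 0.8 to 0.858, so the ranges within and between these groups overlap. Positions are on build mm10, gene values are counts summed over the regions assigned to a gene, errors of log2 changes are standard errors, and errors of CPM are the SD of 2 libraries.

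From day 2 to day 3, the day after the Wnt activator CHIR99021 was added, genes of the caudal epiblast gained accessibility and genes of the early epiblast lost it. Sp5, a direct target of Wnt signalling (chromosome 2, 70474923 to 70477726), rose from 39.9 ± 5.26 to 137 ± 5.66 CPM, a log2 change of 1.78 ± 0.11 (3.44-fold, adjusted p = 1.71e-15). Cdx1, a caudal homeobox gene, rose 3.59-fold (1.84 ± 0.17), and Greb1 rose 1.98-fold (0.98 ± 0.1). Fgf5, a marker of the epiblast, fell 2.4-fold from 75.2 ± 7.43 to 31.2 ± 0.712 CPM (-1.26 ± 0.13, adjusted p = 3.7e-09), Dnmt3b fell 1.85-fold (-0.89 ± 0.14) and Otx2 fell 1.56-fold (-0.65 ± 0.11). A region inside Cdx4 (chromosome X, 103325763 to 103326172) had no counts on day 2 and 10.3 ± 0.36 CPM on day 3, at least 57.5-fold higher. A region inside Cxcl12 (chromosome 6, 117180133 to 117180790) fell 12.3-fold, from 21.2 ± 0.223 to 1.84 ± 0.987 CPM.

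Of the 18 caudal epiblast and neuromesodermal progenitor genes, 12 rose and 6 did not pass (13 rose adjusted over the list alone), with a median log2 change of 0.94. Camera gave the list an adjusted p = 9.88e-09, and adjusted p = 0.102 with an estimated correlation. Hox genes, which set positional identity along the body axis, rose in the anterior and central paralogue groups. In groups 1 to 4, 7 of 12 genes rose, among them Hoxa4 by 6.01-fold (2.59 ± 0.19) and Hoxb4 by 4.28-fold (2.1 ± 0.15), with a list adjusted p = 1.78e-06 and adjusted p = 0.354 with an estimated correlation. In groups 5 to 9, 9 of 13 rose, among them Hoxc5 by 4.52-fold (2.18 ± 0.17) and Hoxa9 by 3.87-fold (1.95 ± 0.16), with a list adjusted p = 1.65e-06 and adjusted p = 0.354 with an estimated correlation. The same numbers, 7 and 9, were called when adjusted over the list alone. In groups 10 to 13, 1 of 12 rose and 1 fell (1 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.279). Inside the HoxA, HoxB, HoxC and HoxD clusters, 13 of 48, 24 of 71, 16 of 61 and 15 of 48 tested regions rose.

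Pluripotency and epiblast genes moved the other way: 11 of 20 fell and 1 rose (11 and 3 adjusted over the list alone), with a median of -0.44, a list adjusted p = 0.00939 and adjusted p = 0.264 with an estimated correlation. Of 19 Wnt targets, 7 rose and 1 fell (8 and 1 adjusted over the list alone). The list had an adjusted p = 0.00514, and adjusted p = 0.354 with an estimated correlation. Among those that rose were Sp5, Cdx1 and Znrf3, a feedback inhibitor of Wnt signalling, 1.77-fold higher (0.82 ± 0.11). Sp5 and Cdx1 are also members of the caudal list. The trunk-to-tail transition list had 9 of 18 genes higher and 1 lower, by either adjustment, with Nr6a1, a trunk regulator, 1.54-fold higher (0.62 ± 0.08). Its list adjusted p = 0.00917 became adjusted p = 0.474 with an estimated correlation, and 6 genes were called higher without day 2 replicate 1, as without day 3 replicate 2. Outside the lists, Ct55 rose 6.46-fold (2.69 ± 0.16) and the Wnt receptor gene Fzd10 rose 2.94-fold (1.56 ± 0.1), while Esm1 fell 2.65-fold (-1.4 ± 0.13).

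The other lists did not pass from day 2 to day 3. Presomitic and paraxial mesoderm had 3 of 20 genes higher and 3 lower (6 and 3 adjusted over the list alone). Neural progenitor and spinal cord had 3 higher and 4 lower of 20 (3 and 5), and TGF-beta and Smad response 2 higher and 4 lower of 20 (2 and 4). Among markers of other cells, 2 endoderm genes rose and 3 fell of 15 (2 and 3). Of lateral plate, heart and blood genes 2 of 14 fell (2), Pecam1 and Nkx2-5. Pecam1 was at -0.12 and not called with a gene window of 10 kb. Nkx2-5 was at -0.5 and not called with cyclic loess. In neural crest 1 of 10 genes fell (1), which was Foxd3 (-0.81 ± 0.13). For fibroblasts, 1 of 14 markers rose and 1 fell, and 2 of 18 housekeeping genes rose, with none of these called when adjusted over the list alone. In this paragraph the values in brackets after a count are those adjusted over the list alone. The fibroblast and housekeeping calls were lost by DESeq2, whose counts were 0 in both, while unadjusted p under 0.05 in edgeR gave 4 fibroblast markers higher and 1 lower, and 5 housekeeping genes higher. Without day 2 replicate 1 the neural list had 1 gene higher and 2 lower and the TGF-beta list none higher and 5 lower, and without day 3 replicate 2 these were 1 and 2, and none and 3. The neural crest list has a median of 0.04 and a mean of -0.02.

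Across all regions, 22833 of 173175 changed from day 2 to day 3, 15309 higher and 7524 lower, and 13801 and 5864 of them changed at least 2-fold. Among 18948 genes, 2325 rose and 1973 fell, but 1376 and 1781 by DESeq2, 2083 and 2142 with cyclic loess and 1293 and 1682 without day 2 replicate 1, so the direction of this excess depends on the fit. Without day 2 replicate 1 the number of changed regions was 13561 and without day 3 replicate 1 it was 13610. Without day 3 replicate 2, 2780 genes changed.

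**Figure D1:**
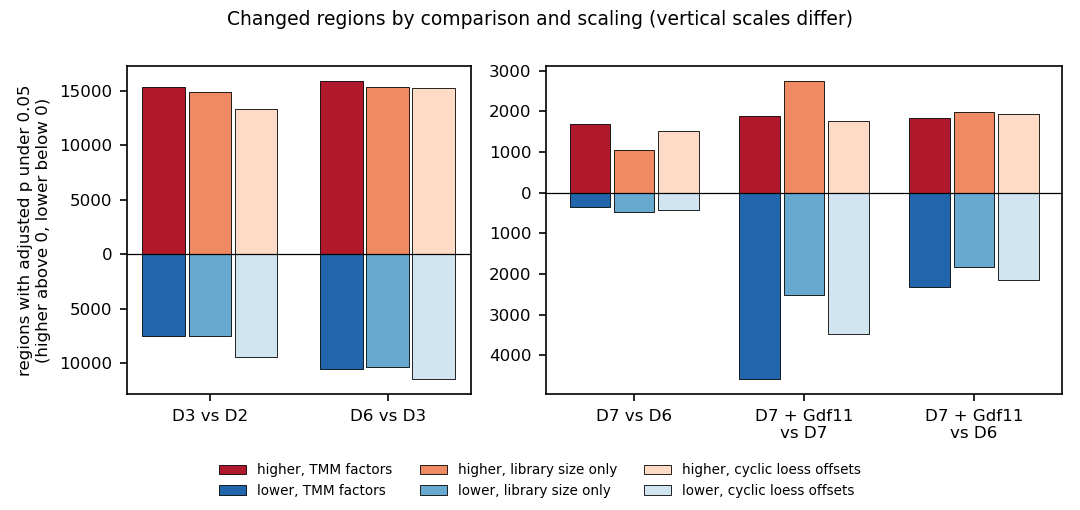
Bars give the number of regions with an adjusted p under 0.05 on the vertical axis, higher above 0 and lower below it, for each of the 5 comparisons on the horizontal axis under 3 scalings, and the vertical scales of the panels differ. With Gdf11 at day 7, 1882 regions were higher and 4589 lower with TMM factors, 2748 and 2521 with library size only, and 1760 and 3468 with cyclic loess offsets.

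Between day 3 and day 6, accessibility fell at 12 of 20 pluripotency and epiblast genes and at Nodal and Lefty2. It rose at 10 of 20 neural progenitor genes. Zfp42, a marker of naive pluripotency, fell 2.39-fold from 80.1 ± 8.42 to 33.4 ± 0.17 CPM (-1.26 ± 0.13, adjusted p = 2.15e-09), and Nanog fell 1.52-fold (-0.61 ± 0.11). Lefty2, an inhibitor of Nodal, fell 2.74-fold (-1.45 ± 0.14) and Nodal itself 2.02-fold (-1.01 ± 0.14). Neurog2, a proneural factor, rose 1.64-fold from 105 ± 7.81 to 172 ± 15.8 CPM (0.71 ± 0.09, adjusted p = 4.66e-07), and the Notch target Hes5 rose 1.64-fold (0.72 ± 0.12). A region 103697 bp from Fam98a (chromosome 17, 75655472 to 75655815) fell 12.3-fold, from 12.9 ± 0.752 to 1 ± 0.217 CPM.

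Of 20 pluripotency and epiblast genes, 12 fell and 8 did not pass (15 fell adjusted over the list alone), with a list adjusted p = 1.78e-06 and adjusted p = 0.102 with an estimated correlation; without day 6 replicate 1 the number was 6. Neural progenitor and spinal cord genes had 10 of 20 higher by either adjustment, with a list adjusted p = 0.00471 and adjusted p = 0.525 with an estimated correlation, and 6 of them higher without day 3 replicate 2 and 4 without day 6 replicate 1. Caudal epiblast genes fell at 8 of 18 and rose at 2 (9 and 2 adjusted over the list alone), with Wnt8a 2.27-fold lower (-1.18 ± 0.12). That list had an adjusted p = 0.0204 and adjusted p = 0.354 with an estimated correlation, and 5 genes fell without day 6 replicate 1, as without day 6 replicate 2. Hox genes went both ways and none of their 3 lists passed. In groups 1 to 4, 3 of 12 rose and 1 fell (adjusted p = 0.255), and in groups 5 to 9, 2 of 13 rose and 1 fell (adjusted p = 0.111). Of 12 genes in groups 10 to 13, 2 rose and 3 fell (adjusted p = 0.3), and all these counts are the same adjusted over the list alone. Hoxd3 rose 1.7-fold (0.77 ± 0.09) and Hoxb5 1.74-fold (0.8 ± 0.21), while Hoxc13 fell 1.7-fold (-0.77 ± 0.12). Without day 6 replicate 1, 1 gene of groups 1 to 4 rose, and without day 3 replicate 2 also 1.

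TGF-beta and Smad response genes rose at 4 and fell at 6 of 20 (5 and 8 adjusted over the list alone; adjusted p = 0.255), with Id2, a target of BMP signalling, 1.45-fold higher (0.54 ± 0.09). Wnt targets rose at 2 and fell at 3 of 19 (2 and 5 adjusted over the list alone; adjusted p = 0.497). The trunk-to-tail list had 3 higher and 4 lower of 18 (4 and 4 adjusted over the list alone) and a list adjusted p = 0.596. Lin28a was 1.59-fold lower (-0.66 ± 0.11) and Mnx1 1.95-fold lower (-0.97 ± 0.13). Presomitic and paraxial mesoderm had 2 of 20 lower by either adjustment (adjusted p = 0.685), 1 of them the segmentation clock gene Hes7 at -0.5 ± 0.1, while the median of the list was 0.03 and its mean -0.11. Endoderm markers had 1 of 15 higher and 5 lower by either adjustment (adjusted p = 0.14), among them Cldn6, 3.21-fold lower (-1.68 ± 0.26). The number lower was 2 without day 3 replicate 2, as without day 6 replicate 1. The 1 that rose was Ttr, 4.02-fold (2.01 ± 0.16), whose change was 0.34 and not called with a gene window of 10 kb. Lateral plate, heart and blood markers rose at 1 of 14, and neural crest markers rose at 1 and fell at 1 of 10. Fibroblast markers rose at 3 and fell at 1 of 14, and housekeeping genes rose at 3 and fell at 1 of 18. These 4 lists had the same counts adjusted over the list alone, and list adjusted p from 0.193 to 0.819. The housekeeping gene that fell was Polr2a, which DESeq2 did not call (-0.36). Hprt, which rose, was at 0.28 and not called with a gene window of 10 kb. Among fibroblast markers the regulator Twist2 rose 1.7-fold (0.76 ± 0.15), and 1 rose without day 3 replicate 2 or without day 6 replicate 1; the list has a median of -0.01 and a mean of 0.05.

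In all, 26378 regions changed between day 3 and day 6, 15887 higher and 10491 lower, with 14502 and 8359 changed at least 2-fold, and 1783 genes rose and 2060 fell (1489 and 1459 by DESeq2). The number of changed regions was 16665 without day 3 replicate 1, 17178 without day 3 replicate 2 and 13605 without day 6 replicate 1. Without day 6 replicate 1, 1828 genes changed, and without day 6 replicate 2, 2378.

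From day 6 to day 7 without Gdf11, accessibility rose at 10 of 20 neural genes. It rose at 7 of 12 Hox genes of groups 1 to 4 and at 4 of 13 of groups 5 to 9. Pax3 and Pax7, factors of the dorsal spinal cord, rose 1.57-fold (0.65 ± 0.08, adjusted p = 4.52e-06, from 199 ± 15.7 to 313 ± 20.1 CPM) and 1.66-fold (0.73 ± 0.1), and the proneural gene Neurog1 rose 1.59-fold (0.67 ± 0.11). Hoxc4 rose 1.51-fold (0.6 ± 0.1), Hoxd3 1.5-fold (0.58 ± 0.09) and Hoxc5 1.72-fold (0.78 ± 0.12). Id2 rose 1.47-fold (0.56 ± 0.08), and outside the lists Iqch rose 2.09-fold (1.06 ± 0.16) and Prr15 1.87-fold (0.9 ± 0.15).

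Of 20 neural progenitor and spinal cord genes, 10 rose (14 rose and 1 fell adjusted over the list alone), 7 with library size only and 8 with cyclic loess; the list had an adjusted p = 1.72e-06 and adjusted p = 0.373 with an estimated correlation. Without day 7 replicate 2 or without day 6 replicate 2, 3 of these genes rose, and 6 without day 6 replicate 1. In Hox groups 1 to 4, 7 of 12 rose (10 adjusted over the list alone), with an adjusted p = 1.78e-06 and adjusted p = 0.354 with an estimated correlation, and 2 rose without day 7 replicate 2. In groups 5 to 9, 4 of 13 rose (6 adjusted over the list alone), with an adjusted p = 0.00386 and adjusted p = 0.486 with an estimated correlation, and 1 rose without day 6 replicate 1, without day 6 replicate 2 or without day 7 replicate 2. In groups 10 to 13, 1 of 12 rose by either adjustment (adjusted p = 0.674), and none with library size only, with cyclic loess or without any 1 of the 4 libraries.

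Pluripotency genes had a lower median of -0.17 as a list (adjusted p = 0.000695, and adjusted p = 0.196 with an estimated correlation). Of the 20 genes 0 passed in edgeR and 0 in DESeq2, 3 fell adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05. Markers of lateral plate, heart and blood were lower as a list (median -0.23, adjusted p = 0.00514, and adjusted p = 0.354 with an estimated correlation). Of these 14 markers 0 were called in edgeR, by DESeq2 or adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Endoderm markers were also lower as a list (-0.15, adjusted p = 0.0145, and adjusted p = 0.354 with an estimated correlation), with 1 of 15 called (2 adjusted over the list alone), a call lost without any 1 of the 4 libraries. Housekeeping genes had a median of 0.17 (0.06 with library size only) and an adjusted p = 0.0432, which was 0.116 with cyclic loess and ran from 0.0337 to 0.571 over 4 alternatives. Of these 18 genes 0 were called in edgeR, by DESeq2 or adjusted over the list alone, and 5 were higher at an unadjusted p under 0.05. The remaining lists did not pass. Caudal epiblast pointed lower as a list (median -0.11, adjusted p = 0.0873) and passed with cyclic loess (adjusted p = 0.0254). It had 2 of 18 higher (4 higher and 5 lower adjusted over the list alone) and presomitic and paraxial mesoderm 4 of 20 higher (5). TGF-beta and Smad response had 5 of 20 higher (5 higher and 1 lower), Wnt targets 1 of 19 (1 and 1) and trunk-to-tail 2 of 18 (3 and 1). Neural crest had 2 higher and 1 lower of 10 (2 and 1), and fibroblasts 1 of 14 lower (1 higher and 1 lower), with the counts adjusted over the list alone in brackets. The medians of the TGF-beta and the Wnt list changed sign with library size only, from 0.08 to -0.03 and from 0.07 to -0.04. The mesoderm list has a median of 0.13 and a mean of -0.04, the Wnt list a mean of -0.05, and the list of Hox groups 10 to 13 a median of 0.03 with a test pointing lower. Without day 7 replicate 2, no caudal, mesoderm, Wnt, trunk-to-tail or crest gene was called, and 2 TGF-beta genes were.

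Changed regions numbered 2045 between day 6 and day 7, 1688 higher and 357 lower, and 1041 and 469 with library size only. A region 29900 bp from Trpa1 (chromosome 1, 14842463 to 14843025) rose 5.8-fold, from 1.22 ± 0.134 to 7.22 ± 0.964 CPM (2.54 ± 0.42). At gene level 680 rose and 128 fell, but 297 rose and 336 fell with library size only. With TMM factors, 18 rose and 24 fell at least 2-fold. The number of changed regions fell to 759 without day 6 replicate 1, 330 without day 6 replicate 2, 1006 without day 7 replicate 1 and 258 without day 7 replicate 2, and that of genes to 324, 152, 375 and 106.

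Gdf11, given from day 6 for 24 h, was compared with untreated day 7 cells. The treated cells had lower accessibility at Hox genes of groups 1 to 9 and at neural genes. The same untreated day 7 libraries gave the rises at Hox and neural genes from day 6 to day 7. High values in those libraries alone would produce both results. With Gdf11 against day 6, 0 of 37 Hox genes passed and 3 of 20 neural genes were lower. Hoxc4 (chromosome 15, 103018097 to 103036856) was 126 ± 12.1 CPM with Gdf11 and 228 ± 26.5 without, 1.81-fold lower (-0.85 ± 0.1, adjusted p = 6.66e-08). Hoxc5 was 1.94-fold lower (-0.96 ± 0.12), Hoxb5 2.03-fold (-1.02 ± 0.19) and Hoxd3 1.7-fold (-0.77 ± 0.09). Neurog2 was 106 ± 9.81 CPM with Gdf11 and 208 ± 7.48 without, 1.96-fold lower (-0.97 ± 0.09, adjusted p = 4.54e-09), Pax7 was 1.8-fold lower (-0.85 ± 0.1) and Hes5 1.74-fold lower (-0.8 ± 0.11). Pmepa1, a feedback inhibitor of TGF-beta signalling, was 1.65-fold higher at 137 ± 5.9 against 83.1 ± 5.03 CPM (0.72 ± 0.1, adjusted p = 1.8e-06). Scaling shifts this comparison: the median of all genes was -0.1 with TMM factors, 0.073 with library size only and 0.004 with cyclic loess, so list medians are also given relative to it.

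In Hox groups 1 to 4, all 12 genes were lower by either adjustment (median -0.75, relative to all genes -0.65), 9 with library size only, 10 with cyclic loess and 11 by DESeq2. The list had an adjusted p = 9.4e-07 and adjusted p = 0.354 with an estimated correlation, and 7 genes were lower without day 7 replicate 2 and 8 without Gdf11 replicate 1. In groups 5 to 9, 9 of 13 were lower by either adjustment (median -0.58, relative -0.48), and 7 with library size only or with cyclic loess. That list had an adjusted p = 0.00076 and adjusted p = 0.468 with an estimated correlation, and 3 genes were lower without day 7 replicate 2, as without Gdf11 replicate 1. Groups 10 to 13 had 1 of 12 genes higher by either adjustment, which was Hoxc11 (0.72 ± 0.18), 0.61 and not called without day 7 replicate 1, and the list did not pass (adjusted p = 0.0766). The median of groups 10 to 13 was 0.19 (relative 0.29), 0.37 with library size only and 0.19 with cyclic loess, opposite in sign to the other groups. Inside the clusters, 6 of 48 regions of HoxA, 14 of 71 of HoxB, 6 of 61 of HoxC and 9 of 48 of HoxD were lower, and 2 of HoxC were higher.

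**Figure D2:**
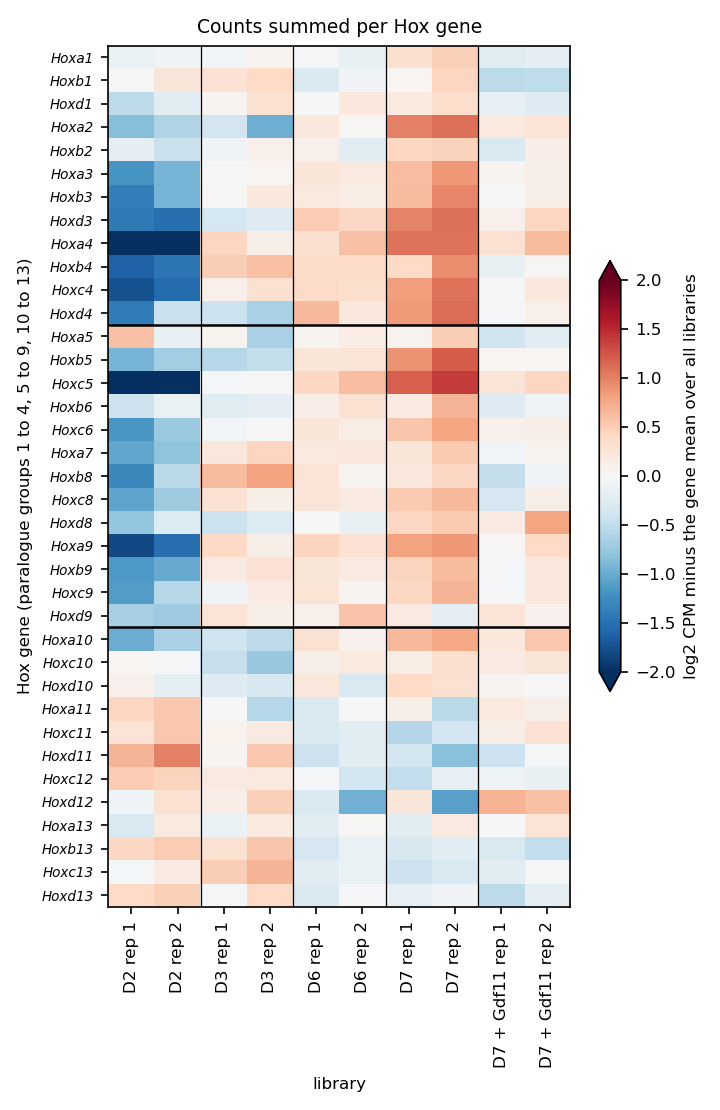
Each cell is the log2 CPM of a Hox gene (vertical axis, ordered by paralogue group) in 1 of the 10 libraries (horizontal axis) minus the mean of the gene over all libraries, in colour from low (blue) to high (red), with TMM scaling. Of 37 Hox genes, 17 rose from day 2 to day 3, 12 rose from day 6 to day 7, and 21 were lower with Gdf11 at day 7. The rise to day 7 and the decrease with Gdf11 share the untreated day 7 libraries, and 0 genes passed with Gdf11 against day 6.

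Of 20 neural progenitor and spinal cord genes, 15 were lower with Gdf11 (17 adjusted over the list alone; median -0.52, relative -0.42), 11 with library size only and 12 with cyclic loess. The list had an adjusted p = 1.74e-07 and adjusted p = 0.354 with an estimated correlation, with 10 genes lower without day 7 replicate 2. Caudal epiblast genes were lower at 10 of 18 (10 lower and 2 higher adjusted over the list alone; median -0.35, relative -0.25), among them Sox2 by 1.58-fold (-0.66 ± 0.09), Cdx2, a caudal regulator of Hox genes, by 1.55-fold (-0.64 ± 0.1), and Greb1 (-0.59 ± 0.1). That list had an adjusted p = 0.0456 and adjusted p = 0.373 with an estimated correlation, the highest of 4 alternatives. The others were 0.0607 with the replicate number as a term, 0.0822 with cyclic loess, and 0.00754 with fry, which tests the list against no change and not against other genes. With library size only 5 of its genes were lower and 3 higher, and 6 were lower without day 7 replicate 1, 4 without day 7 replicate 2 and 6 without Gdf11 replicate 1. Presomitic and paraxial mesoderm had 8 of 20 lower (9 adjusted over the list alone), led by the somite factor Meox1, which fell from 70.7 ± 2.65 to 30.5 ± 4.27 CPM (-1.21 ± 0.15, 2.31-fold). The Notch ligand Dll1 was lower at -0.64 ± 0.1 and Hes7 at -0.65 ± 0.1. Its list did not pass (adjusted p = 0.233, and 0.019 with fry against no change), its median of -0.17 was 0 with library size only, and 3 genes were lower with library size only, 4 with cyclic loess, 3 without day 7 replicate 2 and 5 without Gdf11 replicate 1.

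Members of the TGF-beta and Smad response list went both ways, 3 higher and 5 lower of 20 (5 and 6 adjusted over the list alone), and with library size only 7 were higher and 2 lower. Ldlrad4, an inhibitor of Smad signalling, was 1.6-fold higher (0.68 ± 0.1), while Smad3, a transducer of the signal, was 1.61-fold lower (-0.69 ± 0.1) and Id3 was 1.41-fold lower (-0.49 ± 0.1). The median of -0.04 (0.13 with library size only), the mean of 0.03 and the direction of the test (higher, adjusted p = 0.33) differ in sign. Without day 7 replicate 2, 2 of these genes were higher and 2 lower, and without Gdf11 replicate 1, 5 were higher and 3 lower.

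Wnt targets were lower at 7 of 19 with Gdf11 (9 adjusted over the list alone), among them Axin2 (-0.52 ± 0.09) and Sp5 (-0.45 ± 0.1), but at 2 with library size only or with cyclic loess. The list had an adjusted p = 0.0396 and adjusted p = 0.391 with an estimated correlation, the highest of 4 alternatives. The others were 0.0294 with the replicate number as a term, 0.113 with cyclic loess, and 0.0233 with fry against no change. Without day 7 replicate 2, 2 genes were lower, as without Gdf11 replicate 1, and 4 without day 7 replicate 1. The trunk-to-tail list had 8 of 18 lower by either adjustment and did not pass (adjusted p = 0.0972), with Lin28a 1.73-fold lower (-0.79 ± 0.11). With library size only 2 of its genes were lower, and 4 were without day 7 replicate 1, 1 without day 7 replicate 2 and 3 without Gdf11 replicate 1. Pluripotency genes had a median of 0.13 (relative 0.23), with 1 of 20 higher, not by DESeq2 or without any 1 of the 4 libraries, and none adjusted over the list alone. The list passed (adjusted p = 0.00218) and had adjusted p = 0.196 with an estimated correlation. That gene was Pou5f1 (0.54 ± 0.18).

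None of the 4 lists of markers of other cells passed with Gdf11, though single members did and neural crest had an adjusted p = 0.0459 with fry against no change, and the housekeeping controls passed. Housekeeping genes were lower at 6 of 18 (9 adjusted over the list alone; median -0.28, relative -0.18), but at 1 with library size only or with cyclic loess. They were lower at 1 without day 7 replicate 2 or without Gdf11 replicate 1 and 4 without day 7 replicate 1. Their list passed (adjusted p = 0.0113) and had adjusted p = 0.489 with an estimated correlation. Fibroblast markers were higher at 3 and lower at 2 of 14 by either adjustment (adjusted p = 0.0827). The collagen genes Col3a1 (0.58 ± 0.14) and Col6a1 (0.77 ± 0.18) and S100a4 (1.99 ± 0.54) were higher. Thy1 (-0.89 ± 0.19) and Fbln2 (-0.42 ± 0.11, not called with library size only) were lower. Thy1 was at -0.36 and not called with a gene window of 10 kb. No marker was higher without day 7 replicate 1 and 1 was without day 7 replicate 2 or without Gdf11 replicate 2. Endoderm markers were lower at 2 of 15 by either adjustment (adjusted p = 0.339), which were Ttr (-0.91 ± 0.14, but 0.03 with a gene window of 10 kb) and Trh (-0.43 ± 0.13, not called with library size only). Lateral plate, heart and blood markers had Nkx2-5 higher (0.85 ± 0.23) and Kdr lower (-0.63 ± 0.13) of 14 (adjusted p = 0.111; 4 higher and 1 lower with library size only), neither of them called without day 7 replicate 2 or without Gdf11 replicate 1. Among 10 neural crest markers, Sox9 was lower (-0.56 ± 0.11; adjusted p = 0.596 for the list), and not called without day 7 replicate 2 (-0.37).

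**Figure D3:**
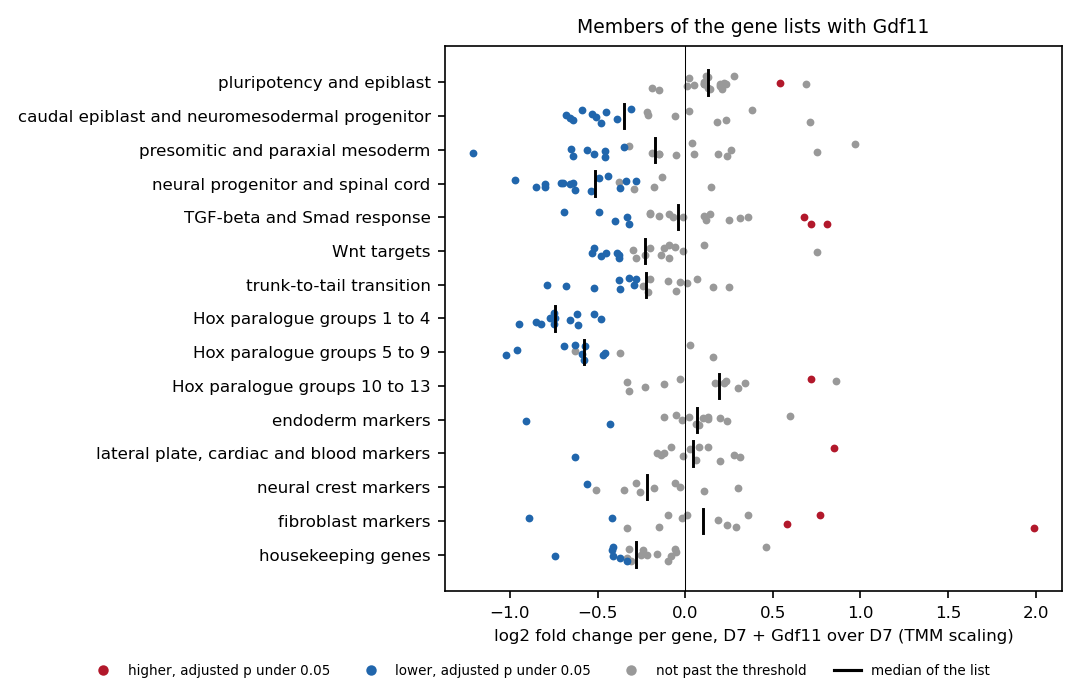
Each point is a gene of the list named on the vertical axis, placed at its log2 fold change of day 7 with Gdf11 over day 7 on the horizontal axis (TMM scaling), coloured by its adjusted p, and bars are list medians. The median is -0.75 in Hox groups 1 to 4 (-0.57 with library size only), -0.52 in the neural list (-0.34) and -0.17 in the mesoderm list (0 with library size only).

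Outside the lists, the largest changes with Gdf11 among abundant genes were decreases with TMM factors. This ranking was not repeated with the other scalings, which shift all genes toward higher values. Ifitm6 fell 2.28-fold (-1.19 ± 0.14), Wfikkn1, which encodes a binding protein of Gdf11 and myostatin, 2.27-fold (-1.18 ± 0.14), and Metrn 2.17-fold (-1.12 ± 0.12). The retinoic acid binding protein gene Crabp2 fell 2.11-fold from 136 ± 19.5 to 64.2 ± 3.56 CPM (-1.08 ± 0.11), and Foxb1 2.06-fold (-1.04 ± 0.1). Among regions, 1 inside Cdh18 (chromosome 15, 23452082 to 23452534) was 18.4 ± 4.11 CPM with Gdf11 and 1.46 ± 0.562 without, 11.9-fold higher (3.57 ± 0.35, adjusted p = 6.02e-10). A region 80968 bp from Sema3d (chromosome 5, 12301902 to 12302484) was 7.77-fold lower (-2.96 ± 0.36), at 2.13 against 16.3 CPM, and 1 at 211313 bp from Rgmb (chromosome 17, 16042268 to 16042851) 7.35-fold lower (-2.88 ± 0.31).

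With TMM factors, 6471 regions differed with Gdf11, 1882 higher and 4589 lower, and 1787 and 2906 of them by at least 2-fold. The excess of lower regions was absent with library size only (2748 higher and 2521 lower) and present with cyclic loess offsets (1760 and 3468). At gene level, 391 were higher and 2143 lower, but 1087 and 526 with library size only and 842 and 762 with cyclic loess, so the direction of the gene excess depends on the scaling. It also turns with TMM factors among genes changed at least 2-fold, of which 93 were higher and 46 lower. The number of changed regions was 3338 without day 7 replicate 1, 1921 without day 7 replicate 2, 1993 without Gdf11 replicate 1 and 3105 without Gdf11 replicate 2. The number of changed genes was 1215, 516 and 815 without the first 3 of these libraries.

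The deposited motif tables give what the authors found enriched in the changed regions, with 414 motifs per table. In the 8962 regions called higher at day 3 than at day 2, the LEF1 motif was in 42.12% against 15.04% of background regions and CDX4 in 44.47% against 17.36%. In the 10615 higher at day 6 than at day 3, Hoxc9 was in 30.07% against 8.8%. The OCT4-SOX2-TCF-NANOG motif came first in the regions called lower at both steps, in 21.6% against 2.68% of 4689 and in 16.82% against 2.59% of 6076 regions. Sox motifs came first in both directions from day 6 to day 7, Sox3 in 75.34% against 45.15% of the 1257 higher regions and Sox6 in 60.39% against 34.31% of the 154 lower regions. In the 523 regions higher with Gdf11, the first motif was Jun-AP1, in 28.11% against 4.86%, and in the 2902 lower regions it was Sox2, in 51.76% against 22.64%. Further tables hold fewer regions for each of these steps, and how those were chosen is not stated. In the 49 such regions higher with Gdf11 the top 3 motifs were Atf7, in 44.9% against 9.53%, Atf1, in 51.02% against 13.09%, and Smad2, in 81.63% against 40.63%.

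**Figure D4:**
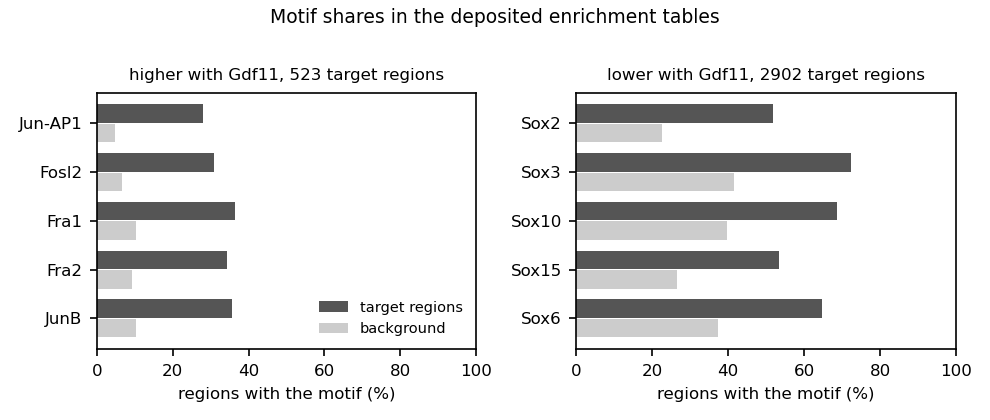
Bars give the percent of target regions (dark) and of background regions (light) that hold each of the first 5 motifs (vertical axis) in the deposited tables for regions higher (left) and lower (right) with Gdf11. Jun-AP1 was in 28.11% of the higher regions against 4.86%, and Sox2 in 51.76% of the lower regions against 22.64%.

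Day 6 was the last stage before Gdf11 was added. Against it, cells on day 7 with Gdf11 had lower accessibility at 6 of 18 caudal genes and higher at 1. Accessibility was higher at Pmepa1 and Ldlrad4. Cdx2 was 59.4 ± 0.332 CPM against 99.5 ± 3.03, 1.68-fold lower (-0.74 ± 0.1, adjusted p = 2.32e-05), Cdx1 1.99-fold lower (-0.99 ± 0.16) and Sp8 1.49-fold lower (-0.58 ± 0.09). Neurog2 was 1.63-fold lower (-0.7 ± 0.09) and Lin28a 1.58-fold lower (-0.66 ± 0.11), while Pmepa1 was 1.67-fold higher (0.74 ± 0.1) and Ldlrad4 1.46-fold higher (0.55 ± 0.1). A region 15960 bp from Emp1 (chromosome 6, 135346380 to 135346801) was 9.15-fold lower (-3.19 ± 0.34).

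Caudal epiblast genes were lower at 6 and higher at 1 of 18 (10 and 1 adjusted over the list alone; adjusted p = 8.84e-05, and adjusted p = 0.196 with an estimated correlation). TGF-beta and Smad response genes were higher at 3 of 20 (5 higher and 1 lower adjusted over the list alone), with a list adjusted p = 0.0196 and adjusted p = 0.516 with an estimated correlation. Wnt targets were lower at 4 and higher at 1 of 19 (5 and 1; adjusted p = 0.0151, and adjusted p = 0.354 with an estimated correlation), and trunk-to-tail genes at 3 of 18 (7; adjusted p = 0.00857, and adjusted p = 0.474 with an estimated correlation). Neural genes were lower at 3 of 20 (4), with a list adjusted p = 0.0396 that ran from 0.0465 to 0.641 over 4 alternatives, with adjusted p = 0.641 with an estimated correlation and 0.0525 with cyclic loess. Fibroblast markers were higher at 3 of 14 (5 higher and 1 lower), Col3a1, Col6a1 and S100a4, with a list adjusted p = 0.0146 and adjusted p = 0.373 with an estimated correlation. None of the 3 was called without day 6 replicate 1, without day 6 replicate 2 or without Gdf11 replicate 2. The Wnt list shares Sp5, Cdx1, T and Wnt3a with the caudal list, so the results of these lists are not separate. Counts in brackets are those adjusted over the list alone.

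None of the 37 Hox genes passed against day 6 in edgeR or by DESeq2 (0 by each). At an unadjusted p under 0.05, 4 were lower in groups 1 to 4, 1 was higher and 2 lower in groups 5 to 9, and 2 were higher in groups 10 to 13. The lists of groups 1 to 4 and 5 to 9 did not pass (adjusted p = 0.0827 and 0.111), though with the replicate number as a term that of groups 1 to 4 passed as lower (adjusted p = 0.0478), and that of groups 10 to 13 did (median 0.08, adjusted p = 0.0426, and adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone, 1 gene was lower in groups 1 to 4, 1 was higher and 1 lower in groups 5 to 9, and 1 was higher in groups 10 to 13. The other lists did not pass. Pluripotency had 1 of 20 lower, presomitic and paraxial mesoderm 2 of 20 lower (3 adjusted over the list alone), and endoderm 1 of 15 lower (2). Of the mesoderm genes, Pax1 was not called with library size only (-0.43) or by DESeq2 (-0.46). The endoderm gene was Ttr, at -0.02 and not called with a gene window of 10 kb. Lateral plate, heart and blood had 1 of 14 lower (3 lower and 1 higher), and neural crest 1 of 10 higher. Of 18 housekeeping genes 0 were called in edgeR, by DESeq2 or adjusted over the list alone, with 1 lower at an unadjusted p under 0.05. The pluripotency list has a median of 0.04 and a mean of -0.04. Without day 6 replicate 1, 4 caudal genes were lower and 1 Wnt target, 1 neural gene and 2 trunk-to-tail genes were lower, and without day 6 replicate 2 these numbers were 4, 1, 1 and 3. Regions changed at 1840 higher and 2312 lower places, and 121 genes were higher and 241 lower, against 260 and 178 with library size only. Depending on which of the 4 libraries was left out, the number of changed regions lay between 1006 (without day 6 replicate 1) and 1984 (without day 6 replicate 2), and that of genes between 45 (without day 6 replicate 1) and 227 (without Gdf11 replicate 2).

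The regions that were lower with Gdf11 were compared with those that had risen between day 3 and day 6, a comparison that shares no library with the first. Of the 4589 lower regions, 2703 (58.9%) were among the 15887 that had risen, against 421 if the calls were independent. Of the same regions 105 were among those that had fallen, against 278. Of the 1882 regions higher with Gdf11, 214 had risen, against 173, and 206 had fallen, against 114. Over all regions the log2 changes of both comparisons had a Spearman correlation of -0.197, and -0.209 and -0.098 between single libraries of replicate 1 and of replicate 2. Independence is not a neutral baseline here. Regions that had risen by day 6 had counts left to lose on day 7, and regions that had fallen had few. How much of these differences follows from this was not tested. Regions are not independent replicates, so no p is given.

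Changed regions lay away from gene ends in all 5 comparisons. With Gdf11, 7.9% of changed and 14.3% of unchanged regions lay within 1 kb of a gene end, an odds ratio of 0.514 over regions, for which no p is given for the same reason. The odds ratios of the other comparisons were 0.515 at day 3 against day 2, 0.444 at day 6 against day 3, 0.308 at day 7 against day 6 and 0.169 for Gdf11 against day 6.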

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

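With 2 libraries per group, leaving out 1 leaves a group with a single library that is assumed to vary like the other groups. Of 1132 gene values re-tested that way, 835 kept their call and 297 lost it. The values re-tested here are those of named genes, Hox genes past the threshold and genes chosen after their values were seen. Many were picked for a small p or a large change, so the shares kept do not stand for all genes called. The replicate term kept all 283 of these calls. DESeq2 kept 258, library size only 257 and cyclic loess 254 of 283. The assignment of regions cost more: a gene window of 10 kb kept 232 of 282, and regions within 1 kb of a gene end kept 67 of 262, with 171 no longer called and 24 of the other sign. At this depth, dispersion and number of libraries, 22% of simulated 2-fold rises of single regions above the median abundance were recovered. What limits the recovery was not separated. The cause of the shifts below was not tested, except where fewer libraries or regions entered the test.

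DESeq2 called 13657 regions at day 3 against day 2, 17048 at day 6 against day 3, 3620 (568 higher, 3052 lower) with Gdf11 against day 7, and 1941 regions and 199 genes with Gdf11 against day 6. With only the 4 libraries compared, 3765 regions changed at day 7 against day 6, 9989 with Gdf11 against day 7 (3890 higher) and 7537 with Gdf11 against day 6. With library size only, 2521 regions were lower with Gdf11 and 1613 genes changed, with cyclic loess 1604 genes changed with Gdf11 and 547 against day 6, and at least 2-fold 2906 regions were lower. Peaks overlapped by at least 50% of both in 62.3%. Libraries with the same replicate number deviated together at correlations of -0.001 to 0.033 over single regions, and the numbers were not taken to pair them. Gene sums were not checked in this way. Replicate 1 had more counts, a lower mitochondrial percent and a higher TMM factor than replicate 2 in all 5 groups, so a shared batch is not excluded. With the replicate block, 1632 genes changed at day 7 against day 6, 3821 with Gdf11 and 1003 with Gdf11 against day 6. Without the block these numbers were 808, 2534 and 362, so a replicate effect on gene sums is not excluded.

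With a gene window of 10 kb, 533 genes changed at day 7 against day 6 and 204 with Gdf11 against day 6. Signs turned for Cyp26a1 at day 3 (-0.04), Ripply2 at day 6 (0.27) and Ttr with Gdf11 (0.03). With regions within 1 kb of a gene end, the 5 comparisons gave 880, 870, 5, 169 and 15 genes. There the sign turned at day 3 for Sox1 (0.31), Msx1 (-0.25), Pmepa1 (0.05), Axin2 (-0.22), Fgf8 (-0.69) and Lrmda (-0.51). At day 6 it turned for Wnt5b (0.15), Fgf8 (0.23), Epha5 (-0.07), Ripply2 (0.28), Pax7 (-0.3), Kdr (-0.14) and Hprt (-0.02). At day 7 it turned for Wnt3a (-1.72), Aldh1a2 (-0.29), Noxa1 (-0.38) and Emid1 (-0.11). With Gdf11 it turned for Aldh1a2 (0.14), Cyp26a1 (1.15), Hoxc8 (0.84), Lrmda (0.4) and Epha4 (0.02), and against day 6 for Wnt3a (-0.41) and Sumf1 (-0.13).

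Of the gene lists called, 0 held with an estimated correlation in any comparison, against 6, 3, 7, 7 and 7. With the self-contained test fry, 3 passed at day 7 against day 6 and 2 with Gdf11 against day 6. Leaving out 1 library at a time gave 13561 to 15923 regions and 2780 to 3050 genes at day 3, 13605 to 18241 regions and 1828 to 2820 genes at day 6, and 258 to 1006 regions and 106 to 375 genes at day 7. With Gdf11 it gave 1921 to 3338 regions (496 to 796 higher, 1425 to 2555 lower) and 516 to 2124 genes, and against day 6 1006 to 1984 regions and 45 to 227 genes.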

Other observations

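Some genes held several regions with lower accessibility with Gdf11, and they were ranked here after their values were seen. The counts grow with the number of regions tested per gene, and 4589 of all 173175 regions were lower. Lrmda held 16 lower regions of 65 tested (14 with cyclic loess) and fell from 583 ± 74.9 to 321 ± 11.8 CPM (-0.86 ± 0.08, n = 2 per group), though its value was 0.4 in regions near gene ends. Next came 9 each in Thsd4 (of 42, -0.92 ± 0.1), Pax7 (of 40), Msi2 (of 72, -0.56 ± 0.08), Rad51b (of 77) and Wwox (of 94). There were 8 each in Hoxd3 (of 19), Hoxc4 (of 26), Gli3 (of 42, -0.45 ± 0.08), Meis2 (of 65, -0.48 ± 0.07) and Auts2 (of 110). The highest number of higher regions in a gene was 5, in Cblb (of 23 tested), Fggy (of 44), Nfia (of 67) and Ptprd (of 101). With cyclic loess these were 3, 2, 5 and 3, the last 3 genes also held 1, 3 and 4 lower regions, and none of the 4 changed as a gene (adjusted p of 0.124 to 0.848). Adamts16 held 3 higher regions of 25 and rose as a gene (0.47 ± 0.12), but not without day 7 replicate 2 (0.34) or Gdf11 replicate 2 (0.42).

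More regions and genes were lower than higher with Gdf11, and the tests of this pattern were chosen only after the result was seen. With library size only, 47.8% of changed regions were lower, but that scaling shifts all regions of a library alike, so the balance had to move and the test decides nothing on the composition factors. With cyclic loess offsets 66.3% of changed regions were lower, which an abundance trend alone would not leave. Of changed genes 47.5% were lower with cyclic loess, which also centres all genes, so whether the gene excess comes from the trend stays open. The trend is in the data: median log2 changes ran from 0.47 in the tenth of regions with the fewest counts to -0.23 in the tenth with the most. The libraries also differed in peak enrichment. The median fold enrichment of peaks was 4.97 and 5.29 with Gdf11, 5.53 and 6.25 at untreated day 7, and 5.13 and 5.53 on day 6. Whether this difference underlies the trend or the calls was not tested. No spike-in decides between the scalings.

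Hox genes of groups 1 to 9 and neural genes were lower with Gdf11, and the tests of this pattern were chosen only after the result was seen. Of 10000 random lists matched on abundance, 0 had a median as low as Hox groups 1 to 4. For groups 5 to 9 and for the neural list the number was 0 too. A trend with the abundance of gene sums is thus not a likely source of these calls. The trend seen over single regions was not matched, and random genes were drawn independently, unlike the clustered Hox genes. The caudal list lay at percentile 0.04 and the housekeeping controls at 1.18 (median -0.28), so low medians were not limited to developmental genes. Hox groups 10 to 13 lay on the other side, at percentile 99 (median 0.19), near the endoderm (98.1) and TGF-beta (98.5) lists. All but the outer tails of the random medians lay between -0.29 and 0.02 for groups 1 to 4, against -0.75 measured. A shift from neural to paraxial mesoderm cells could also lower neural genes. Its prediction of a mesoderm gain was not met: 4 members of the mesoderm list were lower with cyclic loess and none was higher, led by Meox1. The list median was -0.05 with cyclic loess and 0 with library size only, and such sums cannot measure shares of cells. The biological explanation the design offers, an effect of Gdf11 itself, was not separated from other differences between the treated and the untreated cultures. Nor was it separated from the difference in peak enrichment between their libraries.

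AP-1 motifs came first in regions higher with Gdf11, and the test of feeder fibroblasts as their source was chosen only after the result was seen. The median of the fibroblast list lay at percentile 98.1 of matched random lists. Endoderm (98.1) and TGF-beta and Smad response (98.5) lay as high, so the test does not single out fibroblasts. The prediction also asked for Col1a1 and Col1a2 to be higher, and neither was called (-0.15 ± 0.15 and 0.19 ± 0.11). A share of feeder cells could not be told apart from other changes by this list.

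Whether regions that moved from day 6 to day 7 moved less with Gdf11 was tested with libraries used on 1 side only, by a prediction written before the test. Over 8 choices of libraries the Spearman correlation across regions ran from -0.126 to -0.068 with cyclic loess and from -0.161 to -0.097 with TMM factors. The prediction asked for -0.1 or lower in each choice, so the test leaves the question open.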
